A study of Mus musculus with 12 samples.

How the data were processed

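Whole ear skin RNA of 5 mouse genotypes, untreated or 4 h after imiquimod cream, was hybridized to 12 single-colour 60-mer arrays, with 5 untreated and 7 IMQ arrays in 10 groups. Each array received 200 ng of RNA pooled from 6 to 8 mice. Groups were taken from the sample labels. Slide and array position came from the file headers, which place the arrays on 2 slides in 2 scan batches.

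The raw files hold spot values as intensity, per the file headers, made by Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5.1.1. The processed signal is an intensity after background subtraction and detrending within each array, not normalized between arrays, per the file headers. The mean spot signal and the median local background are intensities without further correction, per the file headers. The authors also deposited a table of values, in log2 units, made by background subtraction and a normalization with limma that the design text calls quartile. Its columns share 1 maximum and have medians between 6.37 and 6.38, so they are taken as quantile normalized. Within each array its ranks follow the median signal minus background with a rank correlation of at least 0.999988. The deposited log2 table was used only as an alternative.

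Each array had 59305 spots that were not controls, on 56605 probes. Of these probes 32994 were matched to the reference by accession, 43738 got a reference symbol and 12867 kept the name in the file. Probe coordinates are on mm9, as the files give them. The 298 probes printed at least 8 times on each array had a median SD of 0.051 on the log2 scale within an array. Signal over background sets the depth: 60.1% to 65.7% of spots were well above background, and the lowest log2 value of a probe well above background on an array was taken as the floor of that array, 3.63 to 4.38. Where one side of a comparison lay below background, the fold is given as at least the ratio to that floor. In the text this is applied array by array to the probe used, and genes whose bound lies under the size limit of the comparison or cannot be formed are not given a size, a choice made after the data were seen. Named responses and response differences were also split into the part that lies in the untreated arrays and the rest, likewise after the data were seen, taking the median of the other untreated groups as the baseline of a single-genotype response. The small number of arrays limits the precision.

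The processed signal was put on the log2 scale and quantile normalized between arrays with limma 3.58.1 in R 4.3.3 and the package data.table in version 1.17.8. Left out were 235 probes with an outlier flag on any array. Probes well above background on at least 2 arrays were kept, 37125 in all, and each of 24080 genes, 15782 of them with a gene name, was read on its probe with the highest mean. In a comparison where they are named, other probes of Tlr7, Rph3al, Fkbp5, Rsad2, Ifnar1, Selp, Myh2, Grn, Traf2, Pycard, Ahr, Dgat2l6, Lpl and Mitf had the opposite sign, so these values are those of 1 probe. The same holds for Kcnh2, Cry1, Ccl4, Il1b, Ccr7, Ms4a7, Col1a1, Il19, Irak2, Ikbkg, Hyou1 and Hsp90aa1, where another probe had the same sign and less than 0.5 times the value or bound. Files were read with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.

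The average response was fitted with limma (lmFit and eBayes) on 1 value per genotype and treatment, with genotype as a block and 4 residual degrees of freedom. Dependence on Tlr7 was fitted on the 5 differences, IMQ minus untreated, of Tlr7-deficient against other genotypes, with 3 residual degrees of freedom. The 15 other comparisons are contrasts of a limma fit of the 10 group means. Its 2 residual degrees of freedom come from the repeat IMQ arrays of Tlr7-/-Tlr9-/- and Card14-/-, and single arrays are assumed to vary like them. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, and in the group contrasts also at a difference of at least 1 on the log2 scale. The median SD was 0.048 between repeat arrays, 0.128 between untreated pools of different genotypes and 0.162 in the residuals of the additive genotype and treatment fit.

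The 39 gene lists covered immune and stress pathways, epidermal programmes, metabolism, markers of the cell types of ear skin and sex-linked genes, and were fixed before the data were examined, like the design, the alternatives and the rule for named genes. Lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation, with adjusted p over the lists of one comparison. All p-values are two-sided unless stated otherwise.

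The rule for named genes takes Tlr7, Tlr9 and Card14 in every sample. For each comparison it takes the 10 largest rises and 5 largest falls past the threshold, and for the average response only genes that moved the same way in all 5 genotypes. Symbols that are not gene names are passed over. Values of some genes that the rule takes are not reported here. For each list it takes up to 4 members with the largest change past the threshold, or up to 3 where none passed. Of the named genes those read on repeat probes are left out of the text. Repeat probes, defined after the data were seen, have an alternating GA run of at least 8 bases or a purine run of at least 13, and number 1037 among the filtered probes and 688 among the genes.

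The alternatives were 75th percentile scaling, normexp background correction with an offset of 50, other filters, the mean over probes, the authors' table, other blocks, other spreads and thresholds, and leaving out genotypes or arrays. Calls without repeat probes and calls only of genes well above background in every group were added after the data were seen. The fits and calls were tested on simulated gene values with known changes in 50 genes per size, without repeating normalization, filtering or probe choice. They found 72% of changes of 1 and 90% of changes of 2 on the log2 scale in the average response, and 24% and 70% in the WT response. For dependence on Tlr7 they found 0% and 36%, for Tlr7-/- minus WT 0% and 44%, for Tlr9-/- minus WT 4% and 40%, for Card14-/- minus Tlr7-/-Tlr9-/- 8% and 52%, for the treated comparison 42% and 66% and for untreated Card14-/- 20% and 50%. Unchanged genes made up 1.1% of calls in the WT response and up to 10% in Tlr9-/- minus WT. In the group contrasts the simulated noise was the spread between repeat arrays, so these rates leave out the spread between pools.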

Results

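RNA of whole ear skin was measured on 12 single-colour arrays in mice of 5 genotypes, untreated and 4 h after 62.5 mg of a cream with 5% imiquimod (IMQ), a small-molecule ligand of the receptor TLR7 that is used to induce a psoriasis-like skin inflammation in mice. The genotypes were wild type (WT), Tlr7-/-, Tlr9-/-, Tlr7-/-Tlr9-/- and Card14-/-. CARD14 is a scaffold protein of keratinocytes that signals to NF-kB. Each genotype had 1 untreated array. After IMQ there was 1 array each of WT, Tlr7-/- and Tlr9-/-, and 2 each of Tlr7-/-Tlr9-/- and Card14-/-. Every array held RNA pooled from 6 to 8 mice. Whether the 2 arrays of a genotype share 1 pool is not given in the sources used here, so p-values from them measure the spread between arrays only. The 5 untreated arrays and the IMQ arrays of WT, Tlr7-/- and Tlr9-/- lay on slide 1, and the 4 IMQ arrays of Tlr7-/-Tlr9-/- and Card14-/- on slide 2. Between 60.1% and 65.7% of the 59305 spots were well above background on each array and 0 were saturated. The 75th percentile of the processed signal was 1070 to 1236 on the untreated and 527 to 779 on the IMQ arrays.

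The targeted genes were read in every sample. Tlr7, the receptor for single-stranded RNA and imiquimod, averaged 5.28 ± 0.73 (log2 signal, SD, n = 5, 1 of them below background) in the samples that lack it and 7.81 ± 0.34 (SD, n = 7) in the others, at least 5.71-fold lower. On its other probe it was at least 8.56-fold lower, with 4 of the 5 below background. The highest Tlr7 value in Tlr7-deficient samples, 5.85, lay under the lowest of the others, 7.36. Card14 averaged 9.73 ± 0.14 (SD, n = 3) in Card14-/- and 11.28 ± 0.24 (SD, n = 9) elsewhere, 2.92-fold lower, with 9.89 as the highest value in Card14-/- and 10.83 as the lowest elsewhere. Tlr9, the receptor for unmethylated CpG DNA, averaged 11.14 ± 0.16 (SD, n = 5) in samples labelled as lacking it and 11.25 ± 0.11 (SD, n = 7) in the others, and the ranges overlapped, so this probe does not check that label. The probes lie on the mm9 build at X 163742863 to 163742922 for Tlr7, 9 106128979 to 106129038 for Tlr9 and 11 119206302 to 119206361 for Card14. The average response to IMQ was -0.09 for Tlr7 (adjusted p = 0.843), 0.12 for Tlr9 (0.222) and 0.15 for Card14 (0.36), none past the threshold.

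**Figure D1:**
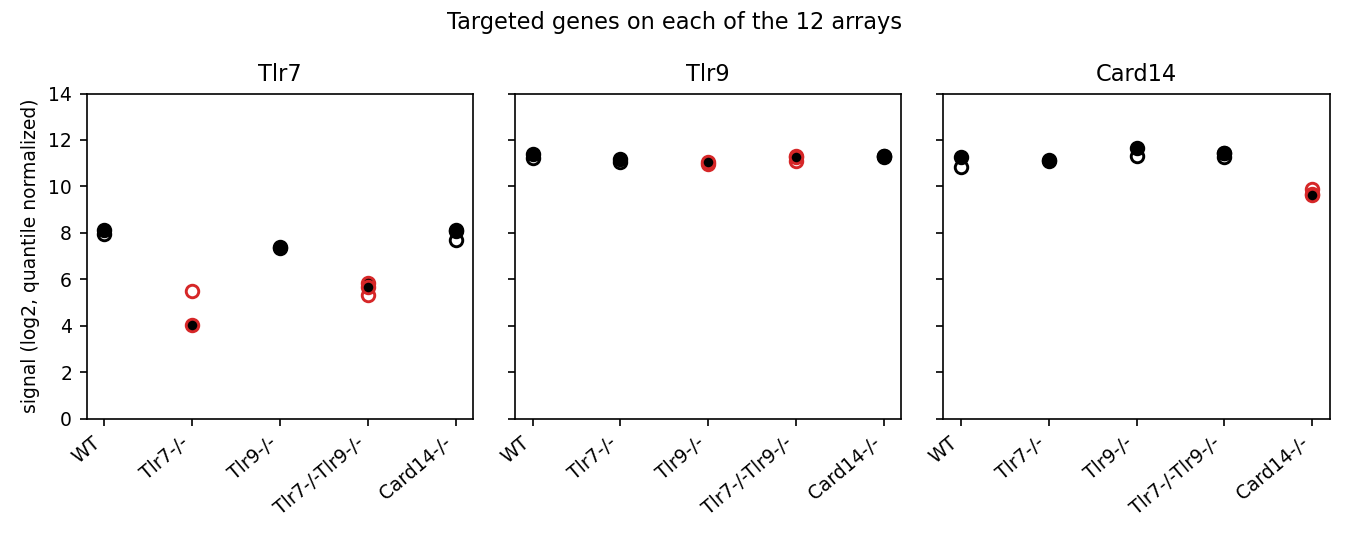
Log2 signal of Tlr7, Tlr9 and Card14 (y axis) on each array by genotype (x axis), with open symbols untreated, filled symbols IMQ and red outlines for the genotype labelled as lacking that gene. Tlr7 and Card14 lay lower in the genotypes that lack them, up to 5.85 and 9.89, and Tlr9 did not separate.

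The average response over the 5 genotypes asks how ear skin 4 h after IMQ cream differs from untreated skin whatever the genotype. No group received cream without imiquimod. In every response given here, effects of imiquimod, of the cream base, of handling and of time therefore cannot be told apart. Array position and signal went with treatment too. On slide 1 the untreated arrays of WT, Tlr7-/-, Tlr9-/- and Tlr7-/-Tlr9-/- lay in row 1 and the IMQ arrays in row 2. The 75th percentile of the processed signal was lower on every IMQ array than on any untreated one. Effects of position and signal cannot be told apart from those of treatment either. Some of the largest rises that went the same way in all 5 genotypes were read on repeat probes and are left out here, a choice made after the data were seen. Ccl20, which draws CCR6-bearing lymphocytes and dendritic cells, rose 23.2-fold (log2 4.54 ± 0.25 SE, adjusted p = 0.00331), and Cxcl1, a neutrophil attractant, rose by log2 4.02 ± 0.14 SE (adjusted p = 0.00331). Epgn, an EGF receptor ligand, rose at least 6.26-fold and Il25, an epithelial cytokine, at least 3.62-fold. Retnlg, a gene of neutrophils, rose at least 3.37-fold. Among the falls were Sprr4 (-3.51), Gsdma2 (at least 11.8-fold), Rnase12 (at least 4.99-fold) and Crygn (at least 4.17-fold), the last 3 below background after IMQ in several genotypes. Kcnh2 fell at least 4.70-fold on the probe used, against -0.17 on its other probe. Tmem52b (3.01) and the transcription factor Fosl1 (2.62) rose, as did Rph3al on 1 probe (2.98), while its other probe had -0.35.

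Early-response lists moved up together. Of 34 immediate early genes, which are transcribed within minutes of a stimulus, 25 rose and 0 fell, and 27 and 0 adjusted over the list alone, with Fosl1 (2.62), Arc (2.03) and Fos (1.55) among them and a median of 0.78. Of 34 NF-kB early response genes 21 rose and 0 fell, and 22 and 0 adjusted over the list alone, with Il6 (at least 2.61-fold), Il1b (1.65), Bcl3 (1.50) and Ptgs2 (1.42) among them and a median of 0.48. Camera gave adjusted p = 1.83e-14 and 7.22e-10, and adjusted p = 0.387 for both with an estimated correlation. Of 24 monocyte and lymphocyte chemokines 9 rose and 1 fell, or 11 and 2 adjusted over the list alone, with Ccl20, Ccl12 (1.80), Ccl2 (1.79) and Ccl7 (1.70) largest. The 1 fall, chosen after its values were seen, was in Ccl11, the eosinophil attractant (-0.60). Their median was 0.35 (adjusted p = 0.00135, and adjusted p = 0.387 with an estimated correlation). With a slide block the adjusted p was 5.36e-11, 2.53e-06 and 0.00422 for these 3 lists, and in the genotypes with both arrays on slide 1 it was 1.46e-09, 2.88e-06 and 0.00279. A slide block takes the effect of IMQ from those same genotypes, with equal list medians, so these are not separate checks, here or below. Of the 16 IL-23/IL-17 and IL-20/IL-36 cytokines Il20, a keratinocyte cytokine, rose (2.15) and 2 fell, with Il1f5 (-0.66) among them, and the list did not shift (median 0.01, adjusted p = 0.77). Il23a, Il17a, Il17f, Ifnb1 and Ifng did not pass the signal filter and were not analysed here. Of 3 neutrophil chemokines only Cxcl1 rose. Their median was -0.53 and their mean 0.60 (adjusted p = 0.519).

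Interferon-stimulated genes, the antiviral programme that type I interferon turns on, also moved up on average, though unevenly between genotypes. Of 42 members 5 rose and 0 fell, or 3 and 0 adjusted over the list alone, with Ifi44 (at least 2.74-fold), Ifi205 (0.98), Slfn5 (0.81) and Ifi204 (0.76) largest and a median of 0.58. The camera test gave adjusted p = 0.000135, and adjusted p = 0.693 with an estimated correlation. The adjusted p was 0.00186 with a slide block and 0.000664 in the slide 1 genotypes. Of 9 interferon and receptor genes 3 rose and 1 fell, with Ifna9 (0.65) and Ifngr1 (0.57) up and Ifnlr1 (-0.37) down (adjusted p = 0.0567).

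Markers of several skin cell types moved as well. Of 11 T cell markers 8 rose and 1 fell, with Cd2 (0.86) and Cd3e (0.80) up, while Cd5 fell by 1.00. Of 10 endothelial markers 6 rose and 1 fell, with the junction genes Cldn5 (0.81) and Esam (0.70) up and Tek down (-0.39, chosen after its values were seen). Of 7 erythroid genes 5 rose, led by Hba-a2 (1.09) and Hba-a1 (1.07). Of 10 dendritic and Langerhans cell markers 4 rose, among them Cd207 (1.20), which encodes langerin, and Ccr7 (0.87). Of 15 monocyte and macrophage markers 3 rose and 1 fell, with C1qb (0.46) and Ms4a7 (0.46) up and Ccr2 (-0.97), the receptor of Ccl2, down. Of 10 Schwann cell and nerve genes 5 fell and 0 rose, with Sox10 (-1.24) and Prx (-0.80) among them. The medians were 0.58, 0.49, 0.74, 0.19, 0.27 and -0.56. Camera gave adjusted p = 0.000909, 0.000903, 0.000704, 0.00794, 0.00535 and 0.00208. With an estimated correlation each of the 6 lists had adjusted p = 0.387 except the endothelial list, at 0.48. Adjusted over the list alone the counts that differed were 7 rises for endothelial, 6 for monocyte and macrophage, and 8 falls for Schwann cell and nerve. With a slide block the 6 adjusted p values were 0.000459, 2.34e-05, 0.0104, 0.00601, 0.00902 and 0.0166, and in the slide 1 genotypes 0.000664, 0.000103, 0.02, 0.0071, 0.02 and 0.02.

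Proliferation and metabolic lists completed the average picture. Of 24 cell cycle genes 10 fell and 0 rose, or 18 and 0 adjusted over the list alone, led by the mitotic genes Bub1b, which fell by 1.00, Kif20a (-0.91), Plk1 (-0.78) and Ccnb2 (-0.69), with a median of -0.45 (adjusted p = 0.000193, and adjusted p = 0.691 with an estimated correlation). Of 12 glucocorticoid-responsive genes 4 rose, among them Fkbp5 (0.69) and Tsc22d3 (0.66), with a median of 0.26 (adjusted p = 0.00186, and adjusted p = 0.387 with an estimated correlation). Of 22 cholesterol synthesis genes 5 rose and 1 fell, or 5 and 2 adjusted over the list alone, with a median of 0.15 (adjusted p = 0.0157, and adjusted p = 0.474 with an estimated correlation). A slide block gave adjusted p = 1.54e-06, 0.0113 and 0.144 and the slide 1 genotypes 5.25e-06, 0.00772 and 0.189, so the cholesterol call was lost in both, which share the same estimate. Among 18 circadian clock genes Nfil3 (0.97) rose and Dbp (-1.05) fell, Cry1 had 1.80 on 1 probe but 0.10 on its other probe, and the list did not shift (adjusted p = 0.491).

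Epidermal and hair follicle lists did not shift on average. Of 35 antimicrobial and stress keratinocyte genes 2 rose and 4 fell, or 1 and 1 adjusted over the list alone, with Lcn2 (1.24) up and Krt6b (-2.09), Defb6 (-1.04) and Sprr1a (-0.98) down. Of 44 keratinocyte differentiation genes 1 rose and 6 fell, or 0 and 6 adjusted over the list alone, among them Rptn (at least 4.43-fold lower), Dsg1a (-0.78) and Krt1 (-0.64), an early differentiation keratin. Both lists had adjusted p = 0.97. The 22 hair follicle genes had 0 rises and 0 falls with a median of -0.50 (adjusted p = 0.519), since they moved in opposite directions between genotypes.

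In total 2512 genes rose and 3839 fell at an adjusted p under 0.05 (limma, genotype as block, 24080 genes, median SE 0.116), of which 2463 and 3787 had the same sign in all 5 genotypes. Of all genes tested, 41.2% had the same sign in all 5, where independent signs give 6.25%. Any difference shared by the IMQ arrays makes signs agree, so this share does not separate a response to IMQ from other shared differences. The rises include 308 genes read on probes with a GA or purine repeat. The count of 6351 fell to 1382 without the Tlr9-/- pair, 2677 without the Tlr7-/- pair, 3258 without the WT pair and 3485 without the Tlr7-/-Tlr9-/- pair. All 12 arrays with a genotype and a slide block gave 12028 genes, which held 2366 of the 2512 rises and 3647 of the 3839 falls, and the genotypes with both arrays on slide 1 shared 1716 and 2217. The fit of all 12 arrays counts repeat arrays as separate values, though they may share a pool. With the slide block it takes its estimate from the slide 1 genotypes. With 75th percentile scaling there were 3241 rises and 3157 falls, so the excess of falls depends on the normalization.

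Whether the response needs Tlr7 was asked by setting the 2 Tlr7-deficient genotypes against the 3 that carry it. Interferon-stimulated genes responded less without Tlr7 in 42 of 42 members, with a median difference of -1.08. Ifit1 (-4.34), Mx2 (-3.46), Mx1 (-3.09) and Oasl1 (-2.97), all antiviral effectors, had the largest differences, with p adjusted over the list alone of 0.0155, 0.0155, 0.00664 and 0.00664, Oasl1 being chosen after its values were seen. Adjusted over the list alone 12 members fell and 0 rose, against 0 and 0 over all genes tested. The camera test gave adjusted p = 3.34e-36, and adjusted p = 0.563 with an estimated correlation. The mean response of the list was 1.17 ± 0.60 (SD, n = 3) with Tlr7 and -0.19 (n = 2) without it (exact two-sided permutation p = 0.2, where 0.1 is the smallest this design allows).

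Of 24 monocyte and lymphocyte chemokines 0 passed over all genes and 3 fell adjusted over the list alone. These are Ccl12 (-1.71, p = 0.0245), Ccl7 (-1.52, p = 0.0188) and Ccl4 (p = 0.0224), whose size is not given since it is partly below background without Tlr7, and the list median was -0.17 (adjusted p = 0.000145, and adjusted p = 0.563 with an estimated correlation). The medians were -0.11 for NF-kB early response genes (adjusted p = 0.00019), -0.48 for antimicrobial and stress keratinocyte genes (3.31e-06), -0.06 for keratinocyte differentiation (0.0402) and -0.10 for inflammasome genes (0.032). They were 0.23 for glucocorticoid-responsive genes (0.00179) and 0.20 for both fatty acid oxidation (0.00177) and sebaceous gland genes (0.00177). With an estimated correlation these were adjusted p = 0.563, 0.758, 0.823, 0.563, 0.563, 0.563 and 0.669, and 0 members of these 7 lists passed even adjusted over the list alone. Hair follicle genes differed most, with a median of -3.82 over 22 genes and 0 members past the threshold (adjusted p = 6.41e-17, and adjusted p = 0.572 with an estimated correlation). Over all genes limma called 0 rises and 0 falls (smallest adjusted p = 0.999, median SE 0.238), with 757 genes at an unadjusted p under 0.05.

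**Figure D2:**
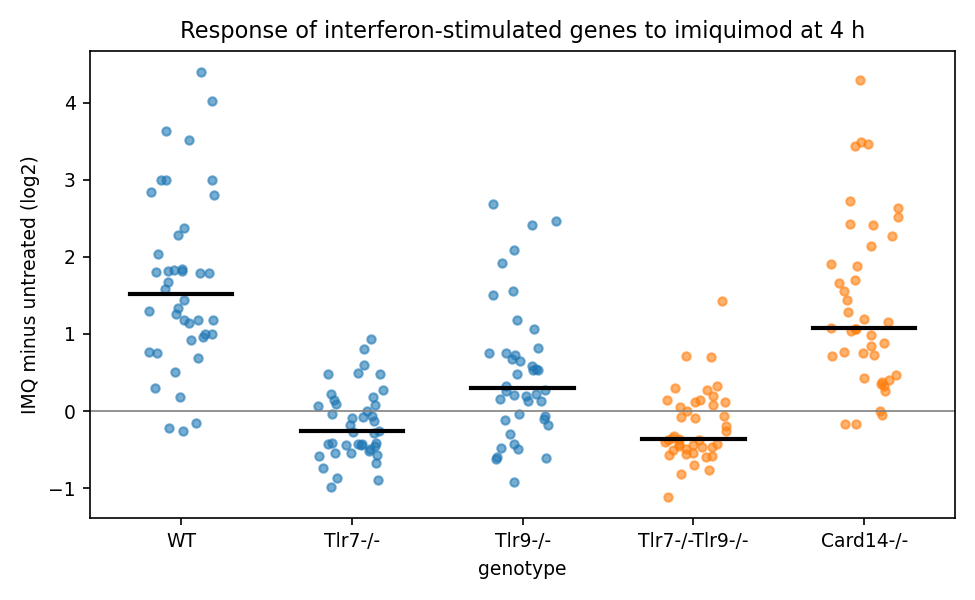
Response to IMQ (log2 IMQ minus untreated, y axis) of the 42 interferon-stimulated genes in each genotype (x axis), 1 point per gene and a black line at the median. Blue points are genotypes with both arrays on slide 1 and orange points those with IMQ arrays on slide 2. The medians were 1.51 in WT, 1.08 in Card14-/- and 0.30 in Tlr9-/-, against -0.26 in Tlr7-/- and -0.36 in Tlr7-/-Tlr9-/-.

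In WT skin interferon-stimulated genes and chemokines moved up as lists. Of 42 interferon-stimulated genes 30 rose and 0 fell, the same counts adjusted over the list alone, with Ifit1 (4.40), Mx2 (4.03), Oasl1 (3.64) and Rsad2 (3.51) largest and a median of 1.51. Of 24 monocyte and lymphocyte chemokines 11 rose and 0 fell, led by the interferon-inducible Cxcl10 (4.45), Ccl20 (4.31), Ccl4 (2.78) and Ccl12 (2.48). Camera gave adjusted p = 1.79e-16 and 9.05e-06, and adjusted p = 0.255 for both with an estimated correlation. Immediate early genes (10 of 34 rose, median 0.79) and NF-kB early response genes (7 of 34 rose, median 0.50) had adjusted p = 4.17e-09 and 2.74e-06, and adjusted p = 0.255 for both with an estimated correlation. Cxcl1 rose (3.62) while the platelet and epithelial chemokines Cxcl5 (at least 4.98-fold) and Ppbp (at least 2.02-fold) fell. Hmox1, the haem oxygenase of oxidative stress, differed by 4.12, but untreated WT stood apart at 9.41, against 12.91 to 13.63 in the other 9 groups and responses of 0.20 to 0.52 in the knockouts, so this value is not read as a response. Cxcl5 too stood apart in untreated WT, at 6.53 against 4.81 at most elsewhere. Tmem52b rose by 5.23 and Rph3al by 4.20 on 1 probe, while its other probe had -0.49, and Tnfsf11, which encodes RANKL, rose at least 8.04-fold.

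Cell type lists moved in WT as well. Hair follicle genes (10 of 22 rose, 0 fell) had a median of 1.15, with Krtap4-16 (1.57) and Krtap3-1 (1.47) largest, and T cell (4 rose, 1 fell of 11), endothelial (2 rose of 10) and dendritic cell markers (2 rose of 10) had medians of 0.94, 0.78 and 0.43. Cell cycle genes (4 of 24 fell, led by Cdk1, -2.16) had a median of -0.53, melanocyte markers (3 of 9 fell, Sox10 -1.35 and Tyrp1 -1.31 among them, the latter mostly from a high untreated value) of -0.79, and fibroblast markers (1 of 11 fell, Postn -2.00) of -0.67. Camera gave these 7 lists adjusted p = 1.13e-06, 0.00409, 0.000275, 0.00401, 0.000387, 0.0123 and 0.0123. With an estimated correlation they had adjusted p = 0.255, 0.336, 0.285, 0.336, 0.285, 0.336 and 0.336. Nerve genes (Sox10 among those that fell) had a median of -0.75 (adjusted p = 0.0268, and adjusted p = 0.336 with an estimated correlation).

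In total 1857 genes rose and 1621 fell in WT (limma adjusted p and at least 1 on the log2 scale, median SE 0.0799), 280 of the rises on repeat probes. The balance depends on the processing, since 75th percentile scaling gave 2380 rises and 911 falls, normexp correction 1200 and 443, and 1454 and 733 came from the authors' table. With the spread taken from the additive genotype and treatment fit 0 calls were left here. The same held in each of the other 4 single-genotype responses and all 5 response differences. That spread also holds differences of the response between genotypes, so the loss of calls does not measure noise alone. Quantile normalization set the median change of all genes to -0.15 in WT and -0.11 in Tlr9-/-, against -0.06 and -0.03 with 75th percentile scaling.

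In Tlr7-/- skin interferon-stimulated genes did not move up (median -0.26), and the leading genes of WT, Ifit1 (-0.74), Mx2 (-0.42), Oasl1 (0.27) and Rsad2 (-0.43), were not past the threshold. Early-response genes did rise, with Ccl20 (3.99), Cxcl1 (3.74), Ccl3 (3.23), Il20 (2.55), Fosl1 (2.14) and Il6 (at least 2.07-fold) among them. Of 34 immediate early genes 9 rose and 0 fell (median 0.63), of 34 NF-kB early response genes 6 rose and 1, Il1a (-1.92), fell (median 0.33), and of 24 chemokines 7 rose and 0 fell (median 0.35). The camera test gave adjusted p = 5.5e-09, 0.000319 and 0.0148, and adjusted p = 0.259, 0.259 and 0.279 with an estimated correlation. Antimicrobial and stress keratinocyte genes went down, 19 of 35 with 1 rise, with Sprr2f (at least 23.8-fold), Krt6b (-4.37) and Lce3a (-3.42) among them and a median of -1.11 (adjusted p = 2.16e-06, and adjusted p = 0.259 with an estimated correlation). Of 44 keratinocyte differentiation genes 6 fell, with the hair-sheath protein Tchh (-5.26) and Rptn (-2.56) largest and a median of -0.19 (adjusted p = 0.00172, and adjusted p = 0.259 with an estimated correlation). Hair follicle genes fell in 18 of 22, led by the inner root sheath keratins Krt25 (-7.35), Krt71 (-7.25) and Krt27 (-6.74), with a median of -4.40 (adjusted p = 2.68e-10, and adjusted p = 0.259 with an estimated correlation).

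The Tlr7-/- pools differed in sex-linked transcripts. Treatment and sex of the pools therefore cannot be separated in the response of this genotype or in its difference from WT. Xist, made from the inactive X of females, was at least 13.5-fold lower in the treated pool, at a value below background. Y-linked Eif2s3y was at least 143-fold, Uty at least 15.4-fold and Ddx3y at least 3.41 on the log2 scale higher there. Defb8 and S100a7l2 were higher too (at least 758-fold and 71.4-fold), but only the untreated Tlr7-/- array stood apart, with Defb8 below background against 11.94 to 13.45 in the other 9 groups and S100a7l2 against 8.06 to 10.78, so neither is read as a response. Of the fatty acid oxidation list Angptl4 (2.39) and Pdk4 (1.35) rose, while its median was 0.02. Of the glucocorticoid-responsive genes Fkbp5 (1.14) rose on 1 probe, and the list had a median of 0.44 (adjusted p = 0.000663, and adjusted p = 0.259 with an estimated correlation). In total 938 genes rose, 217 of them on repeat probes, and 884 fell, against 1105 and 690 with 75th percentile scaling. The count of 1822 fell to 75 without either Card14-/- IMQ array, which carry part of the spread estimate.

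**Figure D3:**
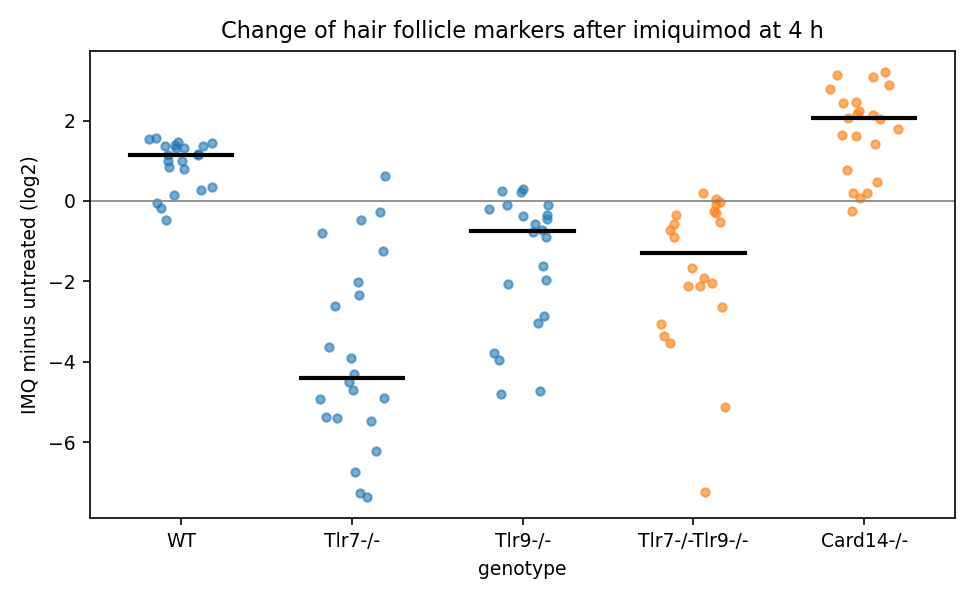
Response to IMQ (log2 IMQ minus untreated, y axis) of the 22 hair follicle genes in each genotype (x axis), 1 point per gene and a black line at the median. Blue points are genotypes with both arrays on slide 1 and orange points those with IMQ arrays on slide 2. Medians ran from -4.40 in Tlr7-/- to 2.05 in Card14-/-.

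In skin labelled Tlr9-/- the interferon-stimulated genes rose in 8 of 42 with 0 falls, led by Oasl1 (2.69), Mx2 (2.47), Ifit1 (2.41) and Rsad2 (2.08), with a median of 0.30 (adjusted p = 0.000192, and adjusted p = 0.3 with an estimated correlation). NF-kB early response genes rose in 10 of 34, with Il1b (3.12, against 0.94 on its other probe) among them and a median of 0.56, and immediate early genes in 14 of 34, led by Fosl1 (2.96) and Arc (2.42), with a median of 0.81. Of 24 chemokines 8 rose and 1 fell, with Ccl20 (3.95), Ccl4 (2.22) and Ccl7 (2.21) up and Cxcl9 (-2.42), a target of interferon-gamma, down from an untreated value of 9.07 that lay above the 5.90 to 8.41 of the other 9 groups, and a median of 0.36. Camera gave these 3 lists adjusted p = 3.64e-08, 1.37e-12 and 0.00238, and adjusted p = 0.3 for each with an estimated correlation. Cell cycle genes fell in 5 of 24 (Bub1b -1.39, Bub1 -1.33, median -0.70) and hair follicle genes in 8 of 22 (Krt71 -4.80, Krt25 -4.73, median -0.75). Their adjusted p values were 1.4e-06 and 0.00101, and adjusted p = 0.3 for both with an estimated correlation. Cxcl1 (4.07) rose, as did Rph3al on 1 probe (3.59, against -0.36 on its other probe), Epgn rose at least 6.14-fold and Retnlg at least 4.02-fold. In total 1232 genes rose, 250 on repeat probes, and 952 fell, against 1678 and 522 with 75th percentile scaling, 742 and 171 with normexp correction and 898 and 317 in the authors' table, and leaving out either Card14-/- IMQ array left 0.

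In Tlr7-/-Tlr9-/- skin 0 of 42 interferon-stimulated genes rose and 1, Igtp (-1.11), fell, with a median of -0.36 (adjusted p = 0.0252, and adjusted p = 0.446 with an estimated correlation). Early-response genes rose, with Ccl20 (5.06), Cxcl1 (4.35), Egr4 (at least 2.15-fold), Fosl1 (2.60) and Lif (2.13) among them. Immediate early genes rose in 10 of 34 (median 0.78) and NF-kB early response genes in 8 of 34 (median 0.32), at adjusted p = 4.45e-11 and 7.43e-07, and adjusted p = 0.345 for both with an estimated correlation. Fkbp5 (1.11) and Angptl4 (1.99), genes of fasting and glucocorticoid responses, rose, and the glucocorticoid-responsive list had a median of 0.50 (adjusted p = 0.000205, and adjusted p = 0.345 with an estimated correlation). Of 7 erythroid genes 4 rose, led by Hbb-b1 (1.16), with a median of 1.01 (adjusted p = 0.000652, and adjusted p = 0.345 with an estimated correlation). Hair follicle genes fell in 11 of 22, with Krt71 (at least 144-fold) and Krt25 (at least 32.6-fold) largest and a median of -1.29 (adjusted p = 6.08e-06, and adjusted p = 0.345 with an estimated correlation), and Xist fell by 1.99. In total 943 genes rose, 191 on repeat probes, and 539 fell, against 391 and 127 with normexp correction. Treatment and slide cannot be separated in this genotype, and leaving out any 1 of the 4 slide 2 arrays left 0 calls.

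In Card14-/- skin interferon-stimulated genes rose in 24 of 42 with 0 falls, led by Ifit1 (4.30), Oasl1 (3.49), Rsad2 (3.46) and Mx2 (3.43), with a median of 1.08. NF-kB early response genes rose in 12 of 34, with Ptgs2 (2.12), Il6 (at least 3.94-fold) and Clec4e (at least 2.83-fold) among them, with a median of 0.55, and immediate early genes in 11 of 34, with Fosl1 (3.08) among them and a median of 0.77. Camera gave adjusted p = 3.51e-17, 5.41e-11 and 4.87e-12, and adjusted p = 0.221 for each with an estimated correlation. Of 24 chemokines 10 rose, led by Ccl20 (5.37), Ccl12 (2.90) and Cxcl10 (2.85), with a median of 0.41 (adjusted p = 0.000287, and adjusted p = 0.3 with an estimated correlation). Antimicrobial and stress keratinocyte genes rose in 6 of 35 and fell in 2, with Saa3 (2.07) up and Krt6b (-1.84) down and a median of 0.21 (adjusted p = 0.00588, and adjusted p = 0.311 with an estimated correlation). Il20 (2.36), a cytokine of the IL-20 family, rose. Hair follicle genes rose in 15 of 22, or 16 adjusted over the list alone, led by Krtap4-16 (3.21), Krt34 (3.14) and Krtap3-1 (3.07), with a median of 2.05 (adjusted p = 5.41e-11, and adjusted p = 0.221 with an estimated correlation). Skeletal muscle genes fell in 4 of 15, led by Myh2 (-1.67) and Myh1 (-1.37), with a median of -0.66 (adjusted p = 3.18e-06, and adjusted p = 0.254 with an estimated correlation). In total 742 genes rose, 139 on repeat probes, and 323 fell, against 648 and 677 without a filter on dim probes. Treatment and slide cannot be separated here either, and the count of 1065 became 220 without either Tlr7-/-Tlr9-/- IMQ array and 0 without either Card14-/- one.

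Genes chosen because they rose in WT were read in the other genotypes. These 1857 genes had a median response of 1.57 in WT, 1.06 in Tlr9-/-, 0.87 in Tlr7-/-, 0.54 in Tlr7-/-Tlr9-/- and 0.51 in Card14-/-. The choice favours WT, and the 1232 genes chosen in Tlr9-/- gave 1.56 in WT, 1.07 in Tlr7-/-, 0.91 in Tlr7-/-Tlr9-/- and 0.65 in Card14-/-. The IMQ arrays of Tlr7-/-Tlr9-/- and Card14-/- lay on slide 2. Over genes well above background on all arrays their responses had an SD of 0.50 and 0.46, against 0.61 to 0.77 in the other genotypes. Slide and genotype cannot be separated in these ranks. In all 5 genotypes 206 genes rose, 93 of them not on repeat probes, and 41 fell.

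**Figure D4:**
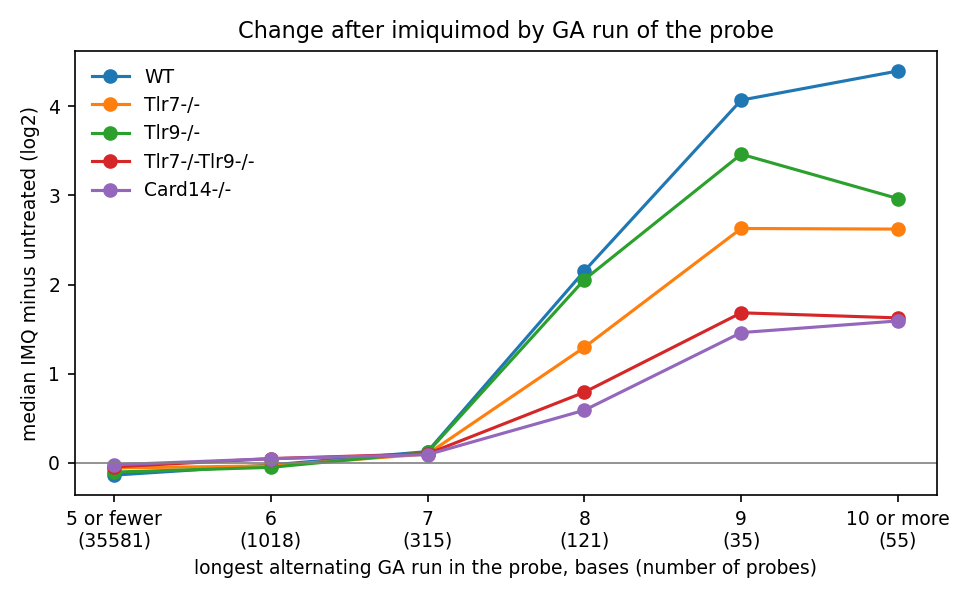
Median response to IMQ (log2 IMQ minus untreated, y axis) of probes by the length in bases of their longest alternating GA run (x axis, number of probes given), 1 line per genotype. In WT the median was 0.13 at a run of 7 and 2.15 at a run of 8.

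Each knockout's response was then set against that of WT, and every such difference uses the same single untreated WT array. In Tlr7-/- minus WT, which asks what the response loses without Tlr7, interferon-stimulated genes fell in 27 of 42, or 30 adjusted over the list alone, led by Ifit1 (-5.14), Mx2 (-4.45), Mx1 (-3.66) and Cmpk2 (-3.55), with a median of -1.56 (adjusted p = 1.64e-27, and adjusted p = 0.263 with an estimated correlation). Of 24 chemokines 4 fell and 1 rose, or 5 and 1 adjusted over the list alone, with Cxcl10 (-4.75) and Ccl4 (at least 8.12-fold, against -0.98 on its other probe) lower and Ccl3 (1.76) higher, and a median of -0.25 (adjusted p = 0.0117, and adjusted p = 0.462 with an estimated correlation). Antimicrobial and stress keratinocyte genes fell in 14 of 35, with Sprr2f (at least 14.2-fold) among them, and 1 rose, or 15 and 2 adjusted over the list alone, with a median of -0.61 (adjusted p = 2.83e-08, and adjusted p = 0.263 with an estimated correlation). Hair follicle genes fell in 17 of 22, or 18 adjusted over the list alone, led by Krt25 (-8.78), Krt71 (-8.43) and Krt27 (-7.74), with a median of -5.89 (adjusted p = 5.11e-20, and adjusted p = 0.263 with an estimated correlation). The sex-linked genes moved with them, with Eif2s3y (at least 161-fold), Uty (at least 12.6-fold) and Ddx3y (at least 8.96-fold) higher and Xist (at least 12.2-fold) lower. A part due to sex of the pools cannot be separated from one due to Tlr7 in this difference. Collagen genes Col1a1 (1.77) and Col5a1 (1.38) were higher in this difference, and fibroblast markers had a median of 0.59 (adjusted p = 0.000225, and adjusted p = 0.445 with an estimated correlation). The larger part of the difference lay between the untreated arrays for Col1a1, Col5a1, Ccl3, Sprr2f and the 3 Y-linked genes. In total 289 genes rose and 541 fell, 74 of the falls on repeat probes, against 165 and 549 with normexp correction and 779 and 917 without a filter on dim probes. The count of 830 was 163 without either Tlr7-/-Tlr9-/- IMQ array and 0 without either Card14-/- one.

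In Tlr9-/- minus WT interferon-stimulated genes fell in 14 of 42, or 20 adjusted over the list alone, led by the interferon-gamma-inducible GTPases Iigp1 (-3.19), Gbp2 (-2.59) and Igtp (-2.31), and Isg15 (-2.31), with a median of -1.10 (adjusted p = 2.23e-24, and adjusted p = 0.315 with an estimated correlation). Untreated Tlr9-/- skin stood above untreated WT in Iigp1 (1.72), Gbp2 (1.50) and Igtp (1.24), which is the larger part of each difference. Cxcl10 (-3.07) and Ccl5 (-1.92) were lower, with a chemokine median of -0.22 (adjusted p = 0.00724, and adjusted p = 0.607 with an estimated correlation), and Il1b (2.37) was higher. These 3 lay mostly between the untreated arrays, where Tlr9-/- stood at 2.26, 1.52 and -2.08 from WT. Hair follicle genes fell in 9 of 22, or 16 adjusted over the list alone, led by Krt25 (-6.16) and Krt27 (-4.94), with a median of -1.82 (adjusted p = 1.41e-17, and adjusted p = 0.315 with an estimated correlation). In total 67 genes rose and 189 fell, or 554 and 694 without a filter on dim probes, and 84 were left with 75th percentile scaling and 0 without any 1 of the 4 slide 2 arrays.

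In Tlr7-/-Tlr9-/- minus WT interferon-stimulated genes fell in 30 of 42, or 32 adjusted over the list alone, led by Ifit1 (-4.94), Mx2 (-3.92), Iigp1 (-3.70) and Cmpk2 (-3.51), with a median of -1.67 (adjusted p = 6.24e-20, and adjusted p = 0.383 with an estimated correlation). Of 24 chemokines 7 fell, led by Cxcl10 (-4.94) and Cxcl9 (-2.94), with a median of -0.51 (adjusted p = 0.000289, and adjusted p = 0.436 with an estimated correlation). Ifnar1, a chain of the type I interferon receptor, was lower (-1.67). Among the 16 IL-23/IL-17 and IL-20/IL-36 cytokines Il21 (at least 2.26-fold), Il1f9 (1.16) and Il1f8 (1.14) were higher, with a median of 0.49 (adjusted p = 0.0412, and adjusted p = 0.464 with an estimated correlation), and the larger part of the Il21 difference, by a small margin, lay between the untreated arrays. Hair follicle genes fell in 15 of 22, with Krt71 (at least 326-fold) and Krt25 (at least 87.9-fold) largest and a median of -2.44 (adjusted p = 1.21e-11, and adjusted p = 0.383 with an estimated correlation). In total 1120 genes rose and 1343 fell, 188 of the falls on repeat probes, against 772 and 1646 with 75th percentile scaling, 395 and 961 with normexp correction and 609 and 1229 in the authors' table, with genotype and slide confounded and 0 calls without any 1 of the 4 slide 2 arrays.

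In Card14-/- minus WT, which asks what the response loses without Card14, interferon-stimulated genes had a small downward median of -0.24 with 2 of 42 lower, Gbp5 (-1.13) and Bst2 (-1.07) (adjusted p = 0.000313, and adjusted p = 0.431 with an estimated correlation). Cxcl9 (-1.91), Cxcl10 (-1.61) and Ccl5 (-1.52) were lower and Ccl20 (1.06), Il19 (at least 2.79-fold) and Saa3 (4.30) higher. For the last 3, as for Selp and Pck1 below, the larger part of the difference lay between the untreated arrays, with 4.03 of the 4.30 for Saa3, so they are not read as a gain of response without Card14. NF-kB early response genes did not shift as a list, with Selp (1.36) among those higher, while 1 of its other probes went the other way. Cell cycle genes rose in 5 of 24, led by Cdk1 (2.44), with a median of 0.43. Melanocyte markers rose in 6 of 9, led by Tyrp1 (2.26), with Oca2 at least 3.42-fold and a median of 1.39, and hair follicle genes rose in 8 of 22, led by Krt34 (1.83), with a median of 0.77. Their adjusted p values were 0.00182, 0.0104 and 0.00182, and adjusted p = 0.431 for each with an estimated correlation. Skeletal muscle genes (Myh2 -1.89, Ttn -1.57) and adipocyte markers (Pck1 -1.33, Cidec -1.02) were lower, with medians of -0.61 and -0.44 (adjusted p = 7.85e-06 and 0.00111, and adjusted p = 0.431 for both with an estimated correlation). In total 1243 genes rose and 1285 fell, 208 of the falls on repeat probes. The near balance depends on the processing, since 75th percentile scaling gave 775 rises and 1623 falls, normexp correction 444 and 945, and 712 and 1177 came from the authors' table. Genotype and slide are confounded, quantile normalization set the median change of all genes to 0.11 here and 0.12 in Tlr7-/-Tlr9-/- minus WT, and 0 calls were left without any 1 of the 4 slide 2 arrays.

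Card14-/- minus Tlr7-/-Tlr9-/- compares 2 responses whose slides match, so that an additive slide effect cancels. Interferon-stimulated genes were higher in 21 of 42 and lower in 0, or 28 and 0 adjusted over the list alone, led by Ifit1 (4.84), Mx2 (3.32), Iigp1 (3.22) and Oasl1 (3.17), with a median of 1.41 (adjusted p = 4.16e-24, and adjusted p = 0.258 with an estimated correlation). Chemokines were higher in 4 of 24, or 6 adjusted over the list alone, namely Cxcl10 (3.33), Ccl12 (2.37), Ccl7 (1.91) and Ccl2 (1.60), with a median of 0.34 (adjusted p = 1.9e-05, and adjusted p = 0.258 with an estimated correlation). Hair follicle genes were higher in 15 of 22, or 16 adjusted over the list alone, with Krt71 (at least 445-fold) and Krt25 (at least 101-fold) largest and a median of 3.88 (adjusted p = 2.56e-18, and adjusted p = 0.258 with an estimated correlation), and so was Tchh (5.28). The fatty acid oxidation gene Pdk4 (-1.42) was lower, with a list median of -0.18 over 23 genes (adjusted p = 0.000211, and adjusted p = 0.258 with an estimated correlation). In total 183 genes rose and 76 fell, or 356 and 392 without a filter on dim probes, and 0 were left without any 1 of the 4 slide 2 arrays.

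The treated arrays of these 2 genotypes, all on slide 2, were also compared directly. Interferon-stimulated genes were higher in treated Card14-/- in 24 of 42, or 25 adjusted over the list alone, led by Ifit1 (4.22), Rsad2 (3.72), Mx2 (3.46) and Mx1 (3.40), with a median of 1.15. Hair follicle genes were higher in 18 of 22, or 19 adjusted over the list alone, with Krt71 (at least 1460-fold) and Krt25 (at least 336-fold) largest and a median of 5.21. Antimicrobial and stress keratinocyte genes were lower in 11 of 35, or 12 adjusted over the list alone, led by Krt6b (-3.02) and Lce3a (-2.25), with a median of -0.73. The camera test gave adjusted p = 5.84e-31, 7.91e-24 and 1.56e-06, and adjusted p = 0.214 for each with an estimated correlation. Chemokines were higher in 5 of 24, led by Cxcl10 (2.98), with Ccl4 at least 6.16-fold and a median of 0.18 (adjusted p = 0.00171, and adjusted p = 0.237 with an estimated correlation). Tlr7 was higher (2.33, adjusted p = 0.00741), Card14 lower (-1.80, adjusted p = 0.00315), and Xist higher (1.92). In total 292 genes rose and 57 fell (median SE 0.0565). The count of 349 was 195 and 194 without Tlr7-/-Tlr9-/- replicate 1 and 2, 45 and 0 without Card14-/- replicate 1 and 2, and 1 with the additive spread.

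Untreated knockouts were compared with the single untreated WT array to read the skin before IMQ. That array stood apart in some genes. Hmox1 was higher in every untreated knockout, by 3.61 in Tlr7-/-, 3.70 in Tlr9-/-, 3.54 in Tlr7-/-Tlr9-/- and 3.50 in Card14-/-, and Saa3, an acute-phase gene, was lower, by -3.02, -4.47, -4.11 and -4.03. Untreated WT was also the highest of the 5 untreated arrays in Krt6b, Stfa1, Il1b, Oca2, Tyrp1, Col1a1, Col2a1, Col3a1 and Col5a1, so part of the differences given for these genes belongs to WT. In untreated Tlr7-/- hair follicle genes were higher in 13 of 22, or 16 adjusted over the list alone, led by Krtap3-1 (2.43) and Krt86 (2.17), with a median of 1.56 (adjusted p = 1.21e-11, and adjusted p = 0.245 with an estimated correlation). Fibroblast markers were lower, led by Col1a1 (-1.76, but -0.87 from the median of the other untreated groups) and Col5a1 (-1.52), with a median of -0.63 (adjusted p = 5.89e-08, and adjusted p = 0.245 with an estimated correlation). Tlr7 was lower (-2.45, adjusted p = 0.0249). Eif2s3y was at least 98.3-fold and Uty at least 9.02-fold lower. Xist stood at 7.89 in this pool, against 6.66 to 6.80 in the other untreated pools, which held both Xist and Y-linked transcripts. Sex of the pools therefore cannot be separated from genotype in the differences of untreated Tlr7-/- from WT.

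In untreated Tlr9-/- skin matrix and pigment genes were lower than in WT. Fibroblast markers fell in 4 of 11, led by Col1a1 (-2.81), Col5a1 (-2.13) and Col3a1 (-1.59), cartilage genes in 4 of 12, led by Col2a1 (-2.24), and melanocyte markers in 5 of 9, with Tyrp1 (-1.39, but -0.38 from the median of the other untreated groups) and Oca2 (at least 2.10-fold) among them, with medians of -0.92, -0.89 and -1.11. Camera gave adjusted p = 1.3e-08, 0.00103 and 2.09e-05, and adjusted p = 0.258 for each with an estimated correlation. Cxcl9 (2.76), Cxcl10 (2.26) and Ccl5 (1.52) were higher and Il1b (-2.08, but -0.97 from the median of the other untreated groups) lower. In untreated Tlr7-/-Tlr9-/- hair follicle genes were lower in 9 of 22, or 15 adjusted over the list alone, led by Krt73 (-2.67), with a median of -1.63 (adjusted p = 7.01e-11, and adjusted p = 0.339 with an estimated correlation), and Tlr7 was lower (-2.60, adjusted p = 0.0408). In untreated Card14-/- antimicrobial and stress keratinocyte genes were lower in 8 of 35, or 10 adjusted over the list alone, led by Saa3, Krt6b (-3.07, but -1.56 from the median of the other untreated groups) and Stfa1 (-2.17), with a median of -0.45 (adjusted p = 5.36e-12, and adjusted p = 0.277 with an estimated correlation). Its interferon-stimulated genes had a median of -0.32 with 0 of 42 past the threshold (adjusted p = 7.6e-07, and adjusted p = 0.277 with an estimated correlation). Card14 stood at -0.93 (adjusted p = 0.0517).

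The untreated comparisons gave 254 rises and 170 falls in Tlr7-/-, 236 and 365 in Tlr9-/-, 75 and 137 in Tlr7-/-Tlr9-/- and 65 and 38 in Card14-/-. Leaving out any 1 of the 4 slide 2 arrays, which carry the spread estimate, left 0 in each. With the additive spread 0, 2, 1 and 0 were left.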

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

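Of the tests in this part, the one on untreated pools was set before its value was seen, and those on slide, on Krtap genes, on sex and hair follicle and on Tlr7 itself were chosen after the result was seen. No group held enough arrays for an array to be tested against its group, so every result here is a difference between genotypes in the response to IMQ, tested as an interaction in the limma fit of 10 groups.

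Interferon-stimulated genes responded less than in WT in Tlr7-/- (median -1.56), Tlr9-/- (-1.10) and Tlr7-/-Tlr9-/- (-1.67), and more in Card14-/- than in Tlr7-/-Tlr9-/- (1.41). A slide effect is argued against as the whole source, since within slide 2 treated Card14-/- stood above treated Tlr7-/-Tlr9-/- by a median of 1.15 over the list (quartiles 0.63 and 2.20). Sex of the pooled mice is argued against only as a constant shift. The untreated Tlr7-/- pool, with Xist and with Uty and Eif2s3y below background, differed from the other untreated pools by a median of 0.008 (quartiles -0.11 and 0.09). This test reads untreated pools and cannot see an effect of sex on the response. Xist was below background in treated Tlr7-/- and at 4.86 and 4.72 in treated Tlr7-/-Tlr9-/-, against 6.55 to 6.87 on the other treated arrays. Sex thus stays open for the response. A response that depends on Tlr7 may account for the pattern, but the design cannot reach an exact p of 0.05. The 2 Tlr7-deficient and 3 other genotypes give an exact two-sided permutation p of 0.2. The mean response of the list was 1.65 in WT and 1.37 in Card14-/-, against 0.50 in Tlr9-/-, -0.18 in Tlr7-/- and -0.20 in Tlr7-/-Tlr9-/-. Setting WT and Card14-/- against the rest parts the list further than Tlr7 does, so p lies above its minimum of 0.1. The lower response in Tlr9-/- is not covered by these tests.

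Hair follicle genes responded less than in WT in Tlr7-/- (median -5.89), Tlr9-/- (-1.82) and Tlr7-/-Tlr9-/- (-2.44), and more in Card14-/- than in Tlr7-/-Tlr9-/- (3.88). A different share of growing follicles among the pools cannot be told apart from other causes by the Krtap genes. The 51 Krtap genes outside the list, with its sign in 5 of 5 genotypes, belong to the same programme and would share the sign under any of them. Before IMQ the list median already stood at 1.73 from the mean of the untreated pools in Tlr7-/- and at -1.64 in Tlr7-/-Tlr9-/-. It stood at 0.04 in WT, 0.17 in Tlr9-/- and -0.13 in Card14-/-. Pools thus differed in these genes without IMQ, on 1 array each. Sex of the pools is argued against in Card14-/-, where the list moved by 2.05 (quartiles 0.94 and 2.46) while Xist moved by 0.05, and stays open in Tlr7-/-, where Xist moved by -5.99, an inexact fall with the treated value below background, and in Tlr7-/-Tlr9-/-, where the list moved by -1.29 and Xist by -1.99. In WT the list moved by 1.15 while Xist moved by -0.15. Dependence on Tlr7 cannot be told apart from these, with an exact two-sided permutation p of 0.2 in a design that cannot reach 0.05. The mean response of this list was 0.91 in WT and 1.75 in Card14-/-, against -1.48 in Tlr9-/-, -3.81 in Tlr7-/- and -1.74 in Tlr7-/-Tlr9-/-. Here too WT and Card14-/- against the rest is a wider split than that by Tlr7.

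Tlr7-/- minus WT had 289 rises and 541 falls. Its sex-linked genes had a median of 5.13. Its largest rise among genes with group means above the highest floor and without a repeat probe was Grn (3.64), chosen after its values were seen and read on 1 of 3 probes, of which another had a WT response of 0.09 against -5.01, so it is read as a value of 1 probe, and its largest fall Krt25 (-8.78). Tlr9-/- minus WT had 67 rises and 189 falls, with Tac4 (2.45) and Krt25 (-6.16) as the largest by the same measure. Tlr7-/-Tlr9-/- minus WT had 1120 rises and 1343 falls, with Grn (4.54) on that probe and Krt71 (-8.41) largest, the latter only bounded, at least 326-fold, since 1 treated Tlr7-/-Tlr9-/- array was below background. Card14-/- minus WT had 1243 rises and 1285 falls, a melanocyte median of 1.39, and Grn (4.75) on that probe and the pseudogene Nlrp1c-ps (-5.06) largest. Card14-/- minus Tlr7-/-Tlr9-/- had 183 rises and 76 falls, with Krt71 (8.86, only bounded at least 445-fold for the same reason) and Nphp4 (-2.42), the latter chosen after its values were seen, largest. The larger part of both the Nlrp1c-ps and the Nphp4 difference lay between the untreated arrays.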

How the results depend on the processing

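The 2 alternatives that leave out repeat probes or genes below background were chosen after seeing the data, and all others before. Each setting was run on the counts it applies to, 18 at most, and on those of the 329 values of named genes. With the mean over probes Pycard became 0.40 and Traf2 -0.02 in the average response, both past no threshold and opposite in sign to the values given, and 0 named values turned direction in any other setting. Unless a cause is given, the cause was not tested.

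The average response of 6351 genes became 9545 with all 12 arrays and a genotype block and 12028 with a slide block added, both counting repeat arrays as separate values. Leaving out 1 genotype pair gave 1382 to 5300, with 1 pair fewer in the fit. The Tlr7 dependence count stayed at 0 under each alternative run.

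With 75th percentile scaling 16 of 18 results stayed within 1.5 times, and Tlr9-/- minus WT had 84 calls and untreated Card14-/- 26. Normexp correction gave 1643 in WT, 906 in Tlr7-/-, 913 in Tlr9-/-, 518 in Tlr7-/-Tlr9-/- and 526 in Card14-/-, with 438, 1356 and 1389 for Tlr9-/-, Tlr7-/-Tlr9-/- and Card14-/- minus WT and 357 for untreated Tlr9-/-. The authors' table gave 2187, 1201, 1215, 756 and 672 for the 5 single-genotype responses in that order. The mean over probes gave 159 for Tlr9-/- minus WT, 45 for untreated Tlr7-/-Tlr9-/- and 54 for untreated Card14-/-. Without a filter on dim probes there were 1696 calls for Tlr7-/- minus WT, 1248 for Tlr9-/- minus WT, 748 for Card14-/- minus Tlr7-/-Tlr9-/-, and 686, 522 and 681 for untreated Tlr7-/-, Tlr7-/-Tlr9-/- and Card14-/-. Requiring every array well above background gave 438 for Tlr9-/- minus WT and 207 for untreated Card14-/-. Without repeat probes untreated Card14-/- had 63 and the other counts stayed within 1.5 times.

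The spread decided the group contrasts. With the spread of the additive fit 0 calls were left in 12 of the 15. The others kept 1 in treated Card14-/- minus Tlr7-/-Tlr9-/-, 2 in untreated Tlr9-/- and 1 in untreated Tlr7-/-Tlr9-/-. The residuals of that fit hold the spread between pools and also any difference of the response between genotypes. A gene whose response differs between genotypes thus widens its own spread. The loss of calls therefore cannot tell noise from such differences. Adjusted p alone, without a size limit, gave 12735, 8189, 9904, 8608 and 6210 for the single-genotype responses, 1306, 6992 and 7588 for Tlr7-/-, Tlr7-/-Tlr9-/- and Card14-/- minus WT, 1031 for the treated comparison and 1309, 2555 and 414 for untreated Tlr7-/-, Tlr9-/- and Tlr7-/-Tlr9-/-. Size alone gave 1659 in Card14-/-, 2570, 2050, 4009 and 4009 for the 4 differences from WT, 1620 for Card14-/- minus Tlr7-/-Tlr9-/-, 789 treated and 990, 1143, 802 and 810 for the 4 untreated knockouts.

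Leaving out 1 repeat array at a time, with 1 residual degree of freedom left, gave 3166 to 3452 in WT, 75 to 1413 in Tlr7-/-, 0 to 1921 in Tlr9-/-, 0 to 220 in Card14-/-, 0 to 163 for Tlr7-/- minus WT and 0 to 195 for the treated comparison, and 0 in the other 9 contrasts. The lone array is assumed to vary like the other groups. A replicate block gave 104 in the treated comparison, where the deviations of the 2 pairs of repeat arrays had a correlation of 0.058 across genes, so nothing pairs them. Of 221 list calls 0 held with an estimated correlation and 225 were made with 75th percentile scaling.

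Signal over background limits genes near the floor: of the 217 named values from group contrasts 37 lost their call when every group compared had to be well above background. Median changes of all genes over 0.1 were -0.15 in WT, -0.11 in Tlr9-/-, 0.12 in Tlr7-/-Tlr9-/- minus WT and 0.11 in Card14-/- minus WT, against -0.06, -0.03, 0.12 and 0.05 with 75th percentile scaling.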

Other observations

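Of the tests in this part, those on slide and normalization of repeat probes were chosen after the result was seen, and the probe pair, split and flanking tests before. Several lists not described so far had members that moved in the average response without a shift of the list. Of 24 Toll-like receptor and adaptor genes 3 rose and 1 fell (adjusted p = 0.252), with the flagellin receptor Tlr5 (1.09) and Irak2 (0.51) up and Tlr12 (at least 1.52-fold) down. Of 17 genes of CARD-BCL10-MALT1 signalling 4 rose and 1 fell (adjusted p = 0.0719), with Malt1 (0.31) up and Ikbkg (-0.54), the NF-kB essential modulator, down, while Traf2 (0.30) turned sign with the mean over probes (-0.02). Of 13 inflammasome genes Casp4 (0.98) rose and 4 fell, or 9 adjusted over the list alone, with Nlrc4 (at least 1.35-fold) and the adaptor Pycard (-0.60) among them (median -0.35, adjusted p = 0.122). With the mean over its probes Pycard had 0.40, so its direction is open. Among oxidative stress genes Osgin1 (0.90) and the metallothioneins Mt2 (0.76) and Mt1 (0.72) rose and Gsta2 (-0.63) fell (adjusted p = 0.491, median -0.02 and mean 0.12). Among heat shock and unfolded protein genes Hyou1 (0.93) and Hsp90aa1 (0.83) rose and Hspa1a (-0.63) fell (adjusted p = 0.97). Ahr (-0.65) and its target Cyp1b1 (-0.66) fell, without a shift of the 8 aryl hydrocarbon receptor targets (adjusted p = 0.525). Angptl4 (1.79) rose and Ehhadh (-0.65) fell among 23 fatty acid oxidation genes (adjusted p = 0.97, median -0.11 and mean 0.05).

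Cell type markers without a shift were as follows. Among 13 neutrophil markers Retnlg (at least 3.37-fold), Fpr2 (1.06) and Trem1 (0.55) rose (adjusted p = 0.0546). Hdc (1.00), which makes histamine, rose and Mrgprb2 (-0.57) fell among 10 mast cell markers (adjusted p = 0.952). Postn (-1.02), Pdgfra (-0.45) and Dcn (-0.41) fell among 11 fibroblast markers (adjusted p = 0.0892). Myh1 (-0.90) and Mb (-0.83) fell and Pvalb (0.71) rose among 15 skeletal muscle genes (adjusted p = 0.491). The lipid synthesis genes Dgat2l6 (-1.06) and Awat2 (-0.80) fell and Soat1 (0.71) rose among 13 sebaceous gland genes (adjusted p = 0.97). Matn3 fell at least 1.50-fold and Hapln1 (0.62) rose among 12 cartilage genes (adjusted p = 0.97). Lpl (-0.47) fell and Lep (0.32) rose among 10 adipocyte markers (adjusted p = 0.491), and Sox10 and Mitf (-0.37) fell among 9 melanocyte markers (adjusted p = 0.519). The 7 plasmacytoid dendritic cell markers had a median of -0.09 and a mean of 0.17 (adjusted p = 0.519) and the 5 sex-linked genes a median of 1.24 (adjusted p = 0.525). The 6 B cell markers had a median of 0.24 (adjusted p = 0.304), which became -0.24 without repeat probes.

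Probes with an alternating GA run of at least 8 bases had a median WT response of 3.43 over 211 probes (quartiles 1.09 and 4.71), against 2.15 at a run of 8 and 0.13 at a run of 7. A slide difference is argued against, since these WT arrays share slide 1, and the choice of normalization too, since 75th percentile scaling gave 3.58. Both normalizations start from the same processed signal, so a difference in signal between arrays is not excluded and was not tested. At a run of 9 the medians were 4.07 in WT, 3.46 in Tlr9-/-, 2.63 in Tlr7-/-, 1.68 in Tlr7-/-Tlr9-/- and 1.46 in Card14-/-. Their IMQ arrays follow the same order in the 75th percentile of the processed signal, lowest in WT. Probes with a CT run of at least 12 bases had a WT median of -1.71. RNA that holds the repeat and binds many probes may be the source, since in 99 genes the repeat probe stood above other probes of the same gene by a median of 2.85 (quartiles 1.05 and 4.58), with 3.17 for the repeat and -0.10 for the other probes. No biological explanation was tested. Whether such RNA changes with treatment stays open.

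Of 9 probes with GCCACCGTCC or GCCACTGTCC, 4 fell by at least 3 in WT, against 16 of 37125 probes, with values below background raised to the floor. The 4 were the probes of Syt10, Grn and Kcnh2 and a probe without a gene name, while Prm1 had -2.22. These sequences were chosen for their falls, after the values were seen, so the count is a description and no test.

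Of 100 splits of the 10 values into 5 and 5 the real one, with 6351 genes in the average response, was the 1 that reached this count, and the highest other gave 4417. The bound of 5% set before on these splits was wrong for this design, since the values are paired by genotype and most of the splits put both values of a genotype on 1 side. The 16 splits that part all pairs are too few for a share under 0.05, with 0 as the highest other.

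A hypothesis was that DNA of another strain kept around each targeted gene may set the level of its neighbours, which held in 1 of 3 loci. Within 10 Mb of Tlr9 lay 8 of 209 genes that differ in both treatments, 3.8% against 1.17% of all genes (one-sided Fisher's exact p = 0.00337), with Abhd14b and Hyal3 lower. Tlr7 had 0 of 36, against 0.3% of all genes (exact p = 1), and Card14 1 of 40, 2.5% against 1.11% (exact p = 0.361). With so few differing genes the tests at Tlr7 and Card14 cannot show absence, and the explanation cannot be told apart from others.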
